A study of Arabidopsis thaliana with 23 samples.

How the data were processed

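RNA sequencing was used to measure transcript levels in 23 libraries of Arabidopsis Col-0, 11 of shoots and 12 of roots, in the 8 groups named in the report. Samples were assigned to groups from the sample labels, and 0 columns of the deposited table were left without a sample. In 1 field of the labels the 3 root samples of PEG with SA190 carry the strain number SA100, while their titles and the columns of the table give SA190, which was followed. Per the labels' protocols, total RNA was depleted of rRNA. Reads were trimmed with Trimmomatic 0.36 and DESeq2 was used with the TAIR10 genome, per the submitters' processing notes, which give no DESeq2 version. The aligner, the counting program, its strand setting and filters are not stated in the sources used here.

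The deposited table holds log2 values for 32833 genes in 23 columns, 1 per library. All columns share the lowest value 4.5753, and the values have the form of a parametric variance-stabilising transform of counts that had been divided by a size factor per library. Turning that form around with its constant r = 23.84 gave whole reads in all columns: 100.0% of 537129 values above the floor lay within 0.05 of a whole read, and the largest distance was 2.1e-07. Recovered reads served for depth, normalised counts (reads over the size factor), means ± SD and the filter. The plan made before the data were examined had assumed log2(value + 1). Because the deposited values are already on a log2 scale, they were tested as deposited, and log2(normalised count + 0.5), + 1 and + 5 were run as alternatives. The transform compresses low values, so its differences understate the folds of weakly expressed genes.

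Within each tissue limma 3.58.1 (R 4.3.3), with an intensity trend and robust moderation, was fitted to the 4 groups, and PEG in mock plants, SA190 on MS, SA190 under PEG, PEG in SA190 plants and their interaction were read from the same fit. Genes needed a mean normalised count of at least 10 in the tissue, which left 18179 in shoots and 18924 in roots. Differences between tissues were tested in a limma fit over all 23 libraries with 19420 genes. p-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 was taken as passing. Groups, comparisons, the filter, the threshold, the 23 gene lists and the rule for naming genes were set before the data were examined.

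For each simple comparison the text could name up to 10 genes with the highest and up to 10 with the lowest log2 difference among those that passed, had a mean at or above the median of the tested genes, had no overlap between the values of the 2 groups and carried a symbol. It could also name up to 4 members of each list with the smallest adjusted p, the 5 smallest p-values where fewer than 5 genes met the first part, and every aquaporin that passed. For interactions and tissue differences up to 3 genes in each direction could be named without the condition on overlap. Members were left out for length, and names outside the rule are marked as chosen later.

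The lists held 392 genes: aquaporins, ABA and drought response, ABA metabolism and core signalling, proline and raffinose metabolism, light harvesting and carbon fixation, salicylic acid response, pattern-triggered immunity and indolic defence, jasmonate, ethylene-jasmonate defence, iron deficiency, phosphate starvation, nitrate uptake, sulfur deficiency, antioxidant enzymes, auxin response, suberin, heat shock, mitotic cell cycle, leaf senescence, anthocyanin synthesis, hypoxia, root markers and seed storage. They were written from general knowledge of the species and not taken from these libraries. Lists were tested with limma's camera at its preset correlation of 0.01 and again with a correlation estimated for each list, adjusted over the list tests together. Symbols and overlapping genes came from the TAIR10.1 annotation, which holds 32548 of the gene identifiers and gives 10810 of them a symbol.

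Alternatives were the pseudocounts named above, no filter, a mean of at least 50, TMM rescaling (trims of 30% and 5%), quantile normalisation, library weights, fits on the groups of 1 comparison alone or on all 23 libraries, the replicate number as a block, a change of at least 2-fold, and each library left out in turn. The 2-fold change was read on the deposited scale, where it is stricter than 2-fold in normalised counts, chiefly for weakly expressed genes. limma with voom weights on the recovered reads and the shallowest library of each tissue left out were added later. 2 planned count-model fits were not run, because the deposited unit is log2, although the recovered reads could have served for them. With the replicate number as a block, SA190 under PEG called 902 shoot genes; whether the numbers pair samples is taken up in the closing section.

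Scripts were tested on simulated data with 200 changed genes. Each gene was given a spread of at least the median of genes at a similar level, and draws were not repeated, so the shares found are rough. Of genes changed 4-fold, the fit found 69.7% for PEG in mock shoots, 75.8% for SA190 on MS in shoots, 57.6% for SA190 under PEG in shoots, 92.4% for PEG in mock roots, 84.8% for SA190 on MS in roots and 93.9% for SA190 under PEG in roots. Of genes changed 2-fold it found 16.4%, 32.8%, 9%, 46.3%, 38.8% and 31.3%. Among its calls in the same order, 0 of 59, 6 of 80, 1 of 45, 7 of 105, 11 of 94 and 3 of 89 were unchanged genes. Of 20 simulated lists left unmoved, camera called 0 in shoots and 1 in roots for PEG in mock plants. Comparisons that share libraries were set beside 50 simulations of unchanged groups. Other calculations and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.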

Results

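Shoots and roots of Arabidopsis thaliana Col-0 seedlings were profiled by sequencing of total RNA from which rRNA had been removed with a Ribo-Zero kit. Seeds were germinated on MS medium that had received Luria broth (mock) or a fresh culture of SA190, a Pseudomonas strain that lives inside plants. By the protocols in the labels, the seedlings moved after 5 days for 16 days to MS alone or to MS infiltrated with 25% polyethylene glycol (PEG), a polymer that lowers the water potential of the medium and is used to imitate drought. The source names in the labels call the seedlings 16 days old, fewer than those times add up to. The 23 libraries made up 8 groups: mock, SA190, PEG and PEG with SA190, each in shoots and in roots. Every group had 3 libraries except PEG with SA190 in shoots, which had 2. The title of the series names drought tolerance, aquaporins and water use as its subject, so each comparison asks what PEG or SA190 did to transcripts in a tissue, and aquaporins are described separately. The labels number the replicates and do not say that they came from separate plates or cultures, so p-values measure the spread between these samples, which may be technical.

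Depth differed widely between libraries. Recovered totals ran from 1.81 M reads in shoot SA190 replicate 1, where 1 read was worth 19.1 normalised counts, to 49.8 M in root SA190 replicate 2. Reads on nuclear genes other than rRNA genes ran from 0.45 M to 46.2 M. Reads without molecular identifiers are not independent molecules, so totals overstate the precision of a value. Genes for rRNA took 0.7% to 59.7% of the reads of a library. In the PEG libraries without SA190 they took 0.7% to 4.87% in shoots and 4.44% to 16.2% in roots. Plastid genes took 35.5% to 63.2% of shoot reads and 1.58% to 7.07% of root reads. Mitochondrial genes took 5.68% to 8.06% of the reads in PEG roots without SA190, against 1.74% to 4.8% in the other roots. In shoots the corresponding ranges were 1.35% to 1.84% with PEG alone and 0.54% to 1.37% in the other libraries. The mean of the root marker genes lay between 5.27 and 6.52 on the log2 scale in every shoot library and between 9.08 and 9.83 in every root library, as the tissue labels require. No 2 libraries were identical: the closest replicates, root PEG 2 and 3, had a correlation of 0.992 across genes.

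**Figure D1:**
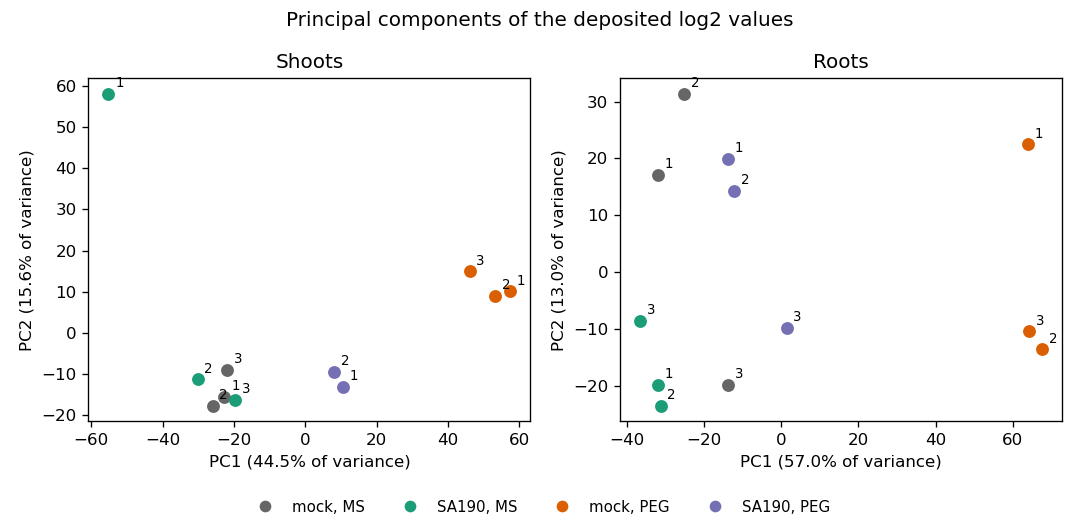
Each point is a library, placed by the first (x axis) and second (y axis) principal component of the deposited log2 values within shoots (left) and roots (right), and numbered by replicate. The first component held 44.5% of the variance in shoots and 57.0% in roots, and on it the PEG roots sat between 63.9 and 67.6 while PEG roots with SA190 sat between -13.8 and 1.4.

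In shoots of mock plants DIN1 (AT4G35770), a dark-inducible gene, stood at 22455 ± 5138 normalised counts (SD, n = 3) on MS and at 377 ± 355 (n = 3) with PEG, a log2 difference of -6.09 ± 0.49 (SE). Differences below are log2 values ± SE on the deposited scale, from limma with 3 PEG and 3 mock libraries. GDPD2 (AT5G41080), a glycerophosphodiester phosphodiesterase, fell by 5.20 ± 0.41. The asparagine synthetase gene ASN1 (AT3G47340) fell by 4.42 ± 0.38 and the hexose transporter gene STP1 (AT1G11260) by 4.35 ± 0.30. DIN10 (AT5G20250), a raffinose synthase-like gene, fell by 3.95 ± 0.30, and TPS11 (AT2G18700), of the trehalose phosphate synthase family, by 3.92 ± 0.26. MCCA (AT1G03090), a methylcrotonyl-CoA carboxylase subunit of leucine breakdown, fell by 3.74 ± 0.21. DAA1 (AT1G64110) rose by 4.50 ± 0.39 and the drought-inducible linker histone gene HIS1-3 (AT2G18050) by 3.88 ± 0.29. DI21 (AT4G15910) rose by 3.20 ± 0.20 and APL3 (AT4G39210), a large subunit of ADP-glucose pyrophosphorylase in starch synthesis, by 2.85 ± 0.17. The lipid transfer protein gene LTP2 (AT2G38530) rose by 3.20 ± 0.25, LTP3 (AT5G59320) by 3.38 ± 0.33 and LTP4 (AT5G59310) by 3.07 ± 0.46. LTP3 and LTP4 are close copies whose reads the counting could have divided, and LTP4 lost its call with pseudocount 0.5. ASN1, STP1, DIN10 and MCCA overlap another annotated gene, and their values are uncertain because the strand used in counting is not given in the sources used here. The same holds for P5CS1, TT19, PAP17, APR1, APR3, PYK10, DREB2A, BHLH101, IAA3, RAB18 and TIP2;1 wherever they are named.

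Of the iron deficiency genes, 17 of 21 tested members rose in PEG shoots and 0 fell (19 and 0 adjusted over the list alone), with a median log2 difference of 1.36. limma's camera test gave the list an adjusted p = 8.75e-13 with the preset correlation and adjusted p = 0.361 with an estimated correlation. Among them OPT3 (AT4G16370), an iron transporter of the phloem, rose by 2.00 ± 0.17 and the nicotianamine synthase gene NAS1 (AT5G04950) by 1.86 ± 0.21. Anthocyanin genes rose in 9 of 12 cases and fell in 0 (10 and 0 adjusted over the list alone), led by TT19 (AT5G17220) at 2.32 ± 0.23 and the regulator MYB75 (AT1G56650) at 2.18 ± 0.29. This list had an adjusted p = 1.61e-05, and adjusted p = 0.391 with an estimated correlation. Phosphate starvation genes rose in 6 of 15 cases and fell in 0 (8 and 0 adjusted over the list alone; adjusted p = 0.0025, and 0.391 with an estimated correlation), including the acid phosphatase gene PAP17 (AT3G17790) at 2.38 ± 0.26. Sulfur deficiency genes rose in 4 of 11 cases (4 and 0 adjusted over the list alone; adjusted p = 0.00816, and 0.426 with an estimated correlation), including APR1 (AT4G04610) of sulfate reduction at 1.79 ± 0.21. Light-harvesting and carbon fixation genes fell in 15 of 23 cases and rose in 0 (16 and 0 adjusted over the list alone), with RBCS3B (AT5G38410) at -1.54 ± 0.24. For this list camera gave an adjusted p = 2.3e-08, and adjusted p = 0.426 with an estimated correlation. Root marker genes rose beside these groups in 3 of 4 cases, with PYK10 (AT3G09260) at 1.66 ± 0.25 (adjusted p = 0.00242, and 0.361 with an estimated correlation). The mean log2 level of the root marker list was 6.13, 6.52 and 6.21 in the PEG shoot libraries and at most 5.83 in the other shoot libraries. Root tissue carried over into shoot samples was not estimated, so its share in the rise of root-expressed genes, iron deficiency genes included, stays open.

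Members of the drought lists went both ways in PEG shoots. Of 25 ABA and drought response genes 6 rose and 4 fell (8 and 5 adjusted over the list alone; adjusted p = 0.199). HB-7 (AT2G46680) rose by 2.49 ± 0.31 and COR15A (AT2G42540) by 2.02 ± 0.32, while COR47 (AT1G20440) fell by 1.94 ± 0.33. The ABA receptor genes PYL5 (AT5G05440) and PYL6 (AT2G40330) fell by 2.61 ± 0.27 and 2.23 ± 0.20. Of the 23 ABA metabolism and signalling genes 4 rose and 4 fell (6 and 4 adjusted over the list alone; adjusted p = 0.565). P5CS1 (AT2G39800), which makes proline, rose by 2.59 ± 0.24, and ERD5 (AT3G30775), which breaks it down, fell by 3.47 ± 0.19. Jasmonate genes fell in 5 of 17 cases (5 adjusted over the list alone), with JAZ9 (AT1G70700) at -2.88 ± 0.24. Auxin response genes fell in 5 of 11 cases and rose in 1 (5 and 1 adjusted over the list alone), with IAA2 (AT3G23030) at -1.56 ± 0.16. Their adjusted p values of 0.0396 and 0.0331 became 0.0563 without shoot mock replicate 3 and 0.0798 without shoot PEG replicate 2. They were 0.581 and 0.391 with an estimated correlation. Altogether 3722 of 18179 tested genes passed an adjusted p of 0.05, 1691 higher and 2031 lower, 1394 of them by at least 2-fold on the deposited scale. Library weights, a fit on the 6 libraries alone and voom on recovered reads gave 6965, 5804 and 5720 genes. Leaving out PEG replicate 1 or PEG replicate 2 gave 2435 or 2481.

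In roots of mock plants PEG nearly removed several transcripts. UMAMIT20 (AT4G08290), of a family of amino acid transporters, stood at 1302 ± 282 normalised counts in mock roots and 5.28 ± 0.88 in PEG roots (SD, n = 3 each). Its neighbour UMAMIT17 (AT4G08300), a close copy, stood at 629 ± 91.7 and 0.66 ± 0.62. The cytochrome P450 genes CYP76G1 (AT3G52970) and CYP93D1 (AT5G06900) had 0 reads in all 3 PEG libraries. They were at least 1410-fold and 1008-fold lower than in mock roots, taking 3 reads over the group as the floor. The BTB-TAZ genes BT1 (AT5G63160) and BT2 (AT3G48360) fell by 4.89 ± 0.26 and 4.21 ± 0.17. The indole glucosinolate methyltransferase gene IGMT1 (AT1G21100) fell by 4.44 ± 0.29, MLP328 (AT2G01520) by 4.23 ± 0.23 and DIN1 (AT4G35770) by 4.38 ± 0.29. ACC2 (AT1G36180), a plastid acetyl-CoA carboxylase, rose from 125 ± 13.1 to 2136 ± 226 normalised counts (SD, n = 3 each) and by 3.69 ± 0.14 on the log2 scale. GMI1 (AT5G24280), a gene induced by DNA damage that overlaps another annotated gene, rose by 3.07 ± 0.13. The nitrate transporter gene NRT2:1 (AT1G08090) rose by 2.84 ± 0.52 and NAS2 (AT5G56080), a nicotianamine synthase gene, by 2.53 ± 0.33. The iron reductase gene FRO2 (AT1G01580) rose by 3.08 ± 0.85 and lost its call without root mock replicate 1, root mock replicate 2 or root PEG replicate 3.

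ABA and drought response genes fell in PEG roots in 16 of 22 cases and rose in 1 (17 and 1 adjusted over the list alone), with a median of -1.44 (camera adjusted p = 1.87e-06, and adjusted p = 0.361 with an estimated correlation). COR47 (AT1G20440) fell by 3.66 ± 0.20, DREB2A (AT5G05410) by 2.36 ± 0.16 and HB-12 (AT3G61890) by 1.90 ± 0.14. NCED3 (AT3G14440), the main ABA synthesis gene of drought, fell by 1.51 ± 0.18. Light-harvesting genes, which are expressed at a low level in roots, fell in 17 of 23 cases (18 adjusted over the list alone; adjusted p = 2.14e-06, and 0.406 with an estimated correlation), with LHCB2.2 (AT2G05070) at -1.77 ± 0.16. With the largest share of shoot RNA that their abundant members allow taken out of each root library, at most 0.639% (root mock replicate 1), 11 fell and their median was -0.56 instead of -1.10. Anthocyanin genes fell in 9 of 11 cases (9 adjusted over the list alone; adjusted p = 0.00249, and 0.516 with an estimated correlation), with DFR (AT5G42800) at -2.01 ± 0.40. Iron deficiency genes rose in 18 of 22 cases and fell in 1 (20 and 1 adjusted over the list alone), with a median of 0.97 (adjusted p = 7.99e-07, and 0.432 with an estimated correlation). AT3G12900, a 2-oxoglutarate-dependent oxygenase gene, rose by 4.29 ± 0.54, and the regulator BHLH101 (AT5G04150) was the member that fell, by 1.15 ± 0.17. Phosphate starvation genes rose in 8 of 16 cases and fell in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.0228, 0.0511 without root PEG replicate 1 and 0.406 with an estimated correlation), with PHT1;4 (AT2G38940) at 1.30 ± 0.13. The vegetative storage protein genes VSP1 (AT5G24780) and VSP2 (AT5G24770), jasmonate markers, fell by 2.72 ± 0.18 and 1.88 ± 0.19. PEG changed 7883 of 18924 tested root genes, 3540 higher and 4343 lower, 1797 of them by at least 2-fold on the deposited scale. Library weights gave 12117 genes, and quantile normalisation moved the share of higher calls from 44.9% to 55.0%.

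The PEG effect in mock plants differed between the tissues for 3711 of 19420 genes, more negative in roots for 2381 and more positive for 1330 (limma over all 23 libraries). HIS1-3 rose by 3.88 in shoots and fell by 2.89 in roots, a difference of -6.77 ± 0.44. For MLP328 the effects were 1.07 in shoots and -4.23 in roots, and for UMAMIT17 0.51 and -4.62, differences of -5.30 ± 0.37 and -5.13 ± 0.33. ASN1, PHI-1 (AT1G35140) and GDPD2 went the other way, by 4.23 ± 0.48, 4.19 ± 0.59 and 3.76 ± 0.49. Anthocyanin genes had a more negative PEG effect in roots in 10 of 12 cases and ABA and drought response genes in 16 of 25, with 0 and 1 more positive. Aquaporins differed in 8 of 27 cases, 6 more negative and 2 more positive. Library weights gave 7887 genes, and quantile normalisation moved the share of more positive calls from 35.8% to 46.1%.

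On MS, SA190 changed few transcripts past the threshold. In shoots the fatty acid dioxygenase gene DOX1 (AT3G01420) rose from 6.79 ± 2.48 to 107 ± 24.9 normalised counts (SD, n = 3 each), by 1.90 ± 0.17 with an adjusted p = 0.0011. DOX1 was the 1 gene of 18179 that passed. Voom also passed 1 gene, and 2484 genes had an unadjusted p below 0.05. A fit on the 6 libraries alone gave 0 genes and DOX1 an adjusted p of 0.14. The next smallest p-values did not pass: AT1G30720 (1.58 ± 0.23), AT1G11210 (1.22 ± 0.18), the jasmonate synthesis gene OPR3 (AT2G06050; -1.02 ± 0.15) and ECS1 (AT1G31580; -1.77 ± 0.27) each had an adjusted p = 0.0619. Leaving out shoot SA190 replicate 2 gave 228 genes and leaving out shoot SA190 replicate 1 gave 17, while a fit on all 23 libraries gave 417, quantile normalisation 4 and library weights 6.

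In roots SA190 on MS changed 60 of 18924 genes, 23 higher and 37 lower, with 3193 at an unadjusted p below 0.05 and 33 by voom, 18.2% of them higher against 38.3%. CDEF1 (AT4G30140), a cutinase gene, rose by 1.38 ± 0.21, the microtubule-associated gene MAP18 (AT5G44610) by 1.07 ± 0.17 and the evening clock gene TOC1 (AT5G61380) by 0.87 ± 0.16. The wall-loosening genes XTH31 (AT3G44990) and EXPA15 (AT2G03090) fell by 1.64 ± 0.29 and 1.44 ± 0.24, CYP79B2 (AT4G39950) of indole glucosinolate synthesis by 1.48 ± 0.19. LHCB2.2 (AT2G05070) fell by 1.09 ± 0.16 and GLDP1 (AT4G33010) of photorespiration by 1.03 ± 0.15. CDEF1 and GLDP1 overlap another annotated gene. These adjusted p values lay between 0.0306 and 0.0356. Each of these genes lost its call with root mock replicate 2, any of the 3 root SA190 replicates or root PEG replicate 3 left out, when 0 genes passed. Leaving out root PEG SA190 replicate 2 gave 7 genes, root PEG replicate 2 gave 22, root PEG replicate 1 gave 114 and root mock replicate 3 gave 978. Library weights gave 6378, a fit on the 6 libraries alone 0, quantile normalisation 99 and a fit on all 23 libraries 28.

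As sets, light-harvesting genes lay lower with SA190 on MS in both tissues, with medians of -0.79 in shoots and -0.63 in roots (camera adjusted p = 1.88e-11 and 5.68e-09, and adjusted p = 0.398 and 0.391 with an estimated correlation). Of 23 members 0 passed in shoots and 2 in roots over all genes, and 14 and 16 adjusted over the list alone, all of them lower. With the same share of shoot RNA taken out of each root library, the root median was -0.25 and 0 members passed, 6 adjusted over the list alone. That share was 0.055% to 0.639% in mock roots and 0.019% to 0.041% in SA190 roots. Anthocyanin genes had medians of -0.39 and -0.72 (adjusted p = 0.004 and 1.16e-08, and 0.432 and 0.391 with an estimated correlation), with 0 members passing over all genes and 1 of 12 and 10 of 11 lower adjusted over the list alone. In shoots the adjusted p was 0.109 without shoot SA190 replicate 2. Jasmonate genes lay lower in shoots, with a median of -0.46, 0 members passing and 7 of 17 lower adjusted over the list alone (adjusted p = 4.09e-06, and 0.391 with an estimated correlation). Leaf senescence genes lay higher, with medians of 0.36 in shoots and 0.30 in roots, 0 members passing in either and 3 higher with 1 lower in shoots and 1 higher in roots adjusted over the list alone (adjusted p = 0.0331 and 0.00392, and 0.426 in both with an estimated correlation). The shoot value rose to at most 0.122 when shoot mock replicate 2 or any of the 3 shoot SA190 replicates was left out. Hypoxia genes lay lower in roots, with a median of -0.24, 1 of 15 members passing and 5 lower adjusted over the list alone (adjusted p = 0.00186, and 0.426 with an estimated correlation). The SA190 effect on MS differed between the tissues for 0 genes by limma and 0 by voom, with 2053 at an unadjusted p below 0.05. Leaving out shoot SA190 replicate 2 gave 187 genes, root mock replicate 3 gave 15 shoot SA190 replicate 1 gave 12 and library weights gave 36.

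In PEG shoots SA190 raised many of the transcripts that PEG had lowered. With 2 libraries of PEG with SA190 against 3 of PEG, DIN1 rose from 377 ± 355 to 17798 ± 4151 normalised counts (SD) and by 5.76 ± 0.55. The beta-galactosidase genes BGAL4 (AT5G56870) and BGAL1 (AT3G13750) rose by 4.01 ± 0.42 and 2.61 ± 0.27. J8 (AT1G80920), a plastid J-domain protein gene, rose by 3.19 ± 0.31, BT1 by 2.92 ± 0.42, ASN1 by 2.87 ± 0.42 and ACBP3 (AT4G24230), an acyl-CoA binding protein gene, by 2.82 ± 0.19. APL3 fell by 2.24 ± 0.19, DI21 by 2.35 ± 0.23, LTP2 by 2.30 ± 0.28 and GBSS1 (AT1G32900), the granule-bound starch synthase gene, by 2.33 ± 0.24. SUS3 (AT4G02280), a sucrose synthase gene, fell by 2.16 ± 0.28 and ADH1 (AT1G77120), alcohol dehydrogenase, by 2.23 ± 0.34. BGAL4, J8, ASN1, ACBP3 and ADH1 overlap another annotated gene and are uncertain for the reason given for ASN1. Iron deficiency genes fell in 10 of 21 cases and rose in 0 (16 and 0 adjusted over the list alone), with a median of -1.02 (camera adjusted p = 3.14e-13, and adjusted p = 0.361 with an estimated correlation). OPT3 fell by 1.89 ± 0.20. Anthocyanin genes fell in 5 of 12 cases (10 adjusted over the list alone; adjusted p = 5.99e-08, and 0.361 with an estimated correlation), with TT19 at -2.02 ± 0.25, a call lost with pseudocount 0.5.

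Phosphate starvation genes fell in 5 of 15 cases in the same comparison (6 adjusted over the list alone; adjusted p = 0.000131, and 0.361 with an estimated correlation), with the non-coding AT4 (AT5G03545) at -2.03 ± 0.23. Sulfur deficiency genes fell in 6 of 11 cases (7 adjusted over the list alone; adjusted p = 2.22e-05, and 0.361 with an estimated correlation), with APR3 (AT4G21990) at -1.70 ± 0.30. Hypoxia genes fell in 3 of 13 cases (5 adjusted over the list alone; adjusted p = 0.00152, and 0.406 with an estimated correlation). Auxin response genes rose in 3 of 11 cases (4 adjusted over the list alone; adjusted p = 0.032, and 0.391 with an estimated correlation), with IAA2 at 1.66 ± 0.18. Without shoot PEG replicate 2 the adjusted p of this list was 0.111. Of the 4 root marker genes 1 fell, PYK10 by 1.09 ± 0.27 (3 adjusted over the list alone). This list had an adjusted p of 0.0182, 0.074 without shoot PEG replicate 2 and 0.391 with an estimated correlation. Light-harvesting genes had 0 members passing of 23 (0 adjusted over the list alone) and a median of 0.32, which was -0.29 after quantile normalisation. SA190 under PEG changed 1411 of 18179 shoot genes, 783 higher and 628 lower, 650 by at least 2-fold on the deposited scale. Without shoot PEG SA190 replicate 1 the count was 318 and without shoot PEG SA190 replicate 2 it was 718. It was 705, 797 and 915 without PEG replicates 1, 2 and 3 and 2325 without shoot SA190 replicate 1. APR3 and PYK10 lost their calls without PEG SA190 replicate 1, and PYK10 also without PEG replicate 2 or 3. Library weights, a fit on the 5 libraries alone, a fit on all 23 and voom gave 3195, 2618, 2281 and 3305 genes.

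In PEG roots, transcripts nearly absent with PEG alone were present when SA190 was there. HAK5 (AT4G13420), the high-affinity potassium transporter gene, stood at 11 ± 2.21 normalised counts with PEG and 1410 ± 478 with PEG and SA190 (SD, n = 3 each), beside 216 ± 17.4 in mock roots. The rise was 129-fold by the means and 4.92 ± 0.20 on the log2 scale. MLP328 rose by 4.67 ± 0.23, the marneral synthase gene MRN1 (AT5G42600) by 4.41 ± 0.33, and UMAMIT20 and UMAMIT17 by 3.99 ± 0.21 and 3.73 ± 0.16. IGMT1 rose by 3.82 ± 0.29 and the beta-galactosidase gene BGAL7 (AT5G20710) by 3.76 ± 0.28. CYP76G1, CYP93D1 and CYP712A2 (AT5G06905), at 0 reads in PEG roots, were at least 1646-fold, 931-fold and 804-fold higher with SA190, against the same floor. ACC2 fell by 3.56 ± 0.14 to 142 ± 27.4 normalised counts (SD, n = 3), GMI1 by 2.80 ± 0.13 and NRT2:1 by 3.03 ± 0.52. UGT74E2 (AT1G05680), a glucosyltransferase gene, fell by 2.61 ± 0.39 and EMB1030 (AT5G22800) by 2.24 ± 0.15. FRO2 fell by 3.19 ± 0.85 and CYP82C4 (AT4G31940), of iron uptake, by 3.67 ± 1.02. Both lost their call without root PEG replicate 1, root PEG replicate 3 or root PEG SA190 replicate 1.

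ABA and drought response genes rose in 18 of 22 cases with SA190 in PEG roots and fell in 1 (18 and 1 adjusted over the list alone), with a median of 1.41 (camera adjusted p = 5.91e-07, and adjusted p = 0.361 with an estimated correlation). COR47 rose by 3.20 ± 0.20, HB-12 by 2.25 ± 0.14, RAB18 (AT5G66400) by 2.23 ± 0.21 and NCED3 by 1.95 ± 0.18. In the list of ABA metabolism and signalling 9 of 24 rose and 3 fell (9 and 4 adjusted over the list alone; adjusted p = 0.137). Iron deficiency genes fell in 15 of 22 cases and rose in 1 (16 and 1 adjusted over the list alone; adjusted p = 2.14e-06, and 0.432 with an estimated correlation), with AT3G12900 at -4.13 ± 0.54. VSP1 rose by 3.42 ± 0.18 and VSP2 by 2.07 ± 0.19. Light-harvesting genes rose in 8 of 23 cases (11 adjusted over the list alone; adjusted p = 0.0025, and 0.544 with an estimated correlation), and LHCB2.2 rose by 1.28 ± 0.16. Anthocyanin genes rose in 6 of 11 cases (7 adjusted over the list alone; adjusted p = 0.0193, 0.0541 without root PEG SA190 replicate 3 and 0.581 with an estimated correlation), with UF3GT (AT5G54060) at 1.35 ± 0.22. SA190 under PEG changed 6162 of 18924 root genes, 3464 higher and 2698 lower, 1305 by at least 2-fold on the deposited scale. Library weights gave 12237 genes, and quantile normalisation moved the share of higher calls from 56.2% to 46.8%.

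Many genes that PEG moved in mock plants moved the other way with SA190 under PEG, 5182 of 7883 in roots and 994 of 3722 in shoots. In roots 2959 genes were lower with PEG and higher with SA190 under PEG and 2223 the reverse, where independent lists would share 795.0 and 504.7. In the same tissue 2 genes were higher in both and 1 lower in both, against 648.0 and 619.2. In shoots the counts were 552 and 442 in opposite directions, against 87.5 and 58.4, and 5 and 1 in the same direction, against 72.8 and 70.2. The 994 shoot genes with opposite directions became 288 and 544 without shoot PEG SA190 replicates 1 and 2, 510 and 586 without PEG replicates 1 and 2 and 1582 without SA190 replicate 1. With single libraries left out, the genes in the same direction ran from 2 to 9 in roots and 0 to 15 in shoots. Both comparisons use the PEG libraries. Across genes, which are not independent replicates, the covariance of the 2 differences was -0.3409 in roots beside -0.0206 in simulated unchanged groups that share the PEG libraries, and -0.2010 in shoots beside -0.0322. The correlations were -0.901 and -0.686, beside -0.499 and -0.446 simulated. The 3 PEG libraries cannot be divided into parts of 2 or more, so part of the excess may come from the shared libraries. SA190 on MS and SA190 under PEG share no library. In roots 18 genes were higher and 14 lower in both, where 4.2 and 5.3 are expected. Another 8 were lower on MS and higher under PEG, where 6.8 are expected. In shoots 0 genes passed in the same direction and 1 in opposite directions, or 32 and 15 without shoot SA190 replicate 2. For PEG in mock plants and SA190 on MS, which share the mock libraries, roots had 13 genes in the same direction and 26 in opposite directions and a covariance of -0.0062 beside 0.0207 simulated. Shoots had 1 and 0 such genes (11 and 2 without shoot SA190 replicate 1, 79 and 22 without replicate 2) and a covariance of 0.0179 beside 0.0324. All these root overlaps with SA190 on MS were 0 genes without root mock replicate 2, any of the 3 root SA190 replicates or root PEG replicate 3. For the 2 SA190 effects, without root mock replicate 3, PEG replicates 1 and 2 and PEG SA190 replicates 1 and 2, the 32 root genes in the same direction became 282, 57, 9, 21 and 1 and the 8 others 137, 16, 4, 5 and 2. Without the same libraries the 13 genes became 380, 21, 6, 9 and 2 and the 26 became 176, 51, 7, 16 and 2.

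PEG also acted in plants that carried SA190, on fewer genes. In shoots GDPD2 fell by 3.76 ± 0.46 with PEG (2 PEG and 3 MS libraries), the threonine aldolase gene THA1 (AT1G08630) by 2.52 ± 0.24 and ERD5 by 2.26 ± 0.22. The branched-chain aminotransferase gene BCAT-2 (AT1G10070) fell by 2.19 ± 0.21, while P5CS1 rose by 1.95 ± 0.26. THA1 and BCAT-2 overlap another annotated gene. In roots DIN1 fell by 3.01 ± 0.29, BT1 by 2.42 ± 0.26, BT2 by 2.06 ± 0.17 and the transcription factor gene RAV1 (AT1G13260) by 2.10 ± 0.22. HAK5 rose by 2.04 ± 0.20 in these roots, LTP3 by 2.31 ± 0.19, EXPA15 by 1.64 ± 0.24 and XTH31 by 1.96 ± 0.29. Leaf senescence genes fell in 5 of 10 cases in roots (5 adjusted over the list alone; adjusted p = 0.000131, and 0.398 with an estimated correlation). Anthocyanin genes rose in 3 of 11 cases in roots (6 adjusted over the list alone; adjusted p = 0.000677, and 0.432 with an estimated correlation). Hypoxia genes rose in 5 of 15 and fell in 1 (7 and 2 adjusted over the list alone; adjusted p = 0.00384, and 0.433 with an estimated correlation). Mitotic genes had 1 of 14 members higher in roots (3 adjusted over the list alone; adjusted p = 0.000513, and 0.361 with an estimated correlation).

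Counts for PEG in SA190 plants were 828 of 18179 in shoots, 509 higher and 319 lower, and 1410 of 18924 in roots, 514 higher and 896 lower. The shoot count was 54 without PEG SA190 replicate 1, 479 without PEG SA190 replicate 2 and 1523 without shoot SA190 replicate 3. It was 88 in a fit on the 5 libraries alone and 2102 in a fit on all 23, and with voom 46.6% of its calls were higher against 61.5%. The root count was 723 and 686 without SA190 replicates 1 and 2, 685, 796 and 922 without PEG SA190 replicates 1, 2 and 3. It was 2141 in a fit on the 6 libraries alone and 9276 with library weights. Between the PEG effect in mock plants and in SA190 plants, which share no library, the correlation across genes was 0.532 (Spearman 0.453) in shoots and 0.426 (Spearman 0.402) in roots. With single libraries left out it ran from 0.454 to 0.552 and from 0.311 to 0.480. The slope of the effect in SA190 plants on that in mock plants was 0.403 in shoots and 0.230 in roots, and 0.476 and 0.251 after allowing for noise in the x values. Both effects passed in the same direction for 515 shoot genes and in opposite directions for 15, and for 934 and 119 root genes. The 515 became 50 and 276 without shoot PEG SA190 replicates 1 and 2 and 854 without shoot SA190 replicate 3, and the 15 ran from 0 to 28. In roots the 934 became 543 and 508 without SA190 replicates 1 and 2 and 542, 576 and 577 without PEG SA190 replicates 1, 2 and 3. The 119 became 67, 54 and 78 without SA190 replicates 1, 2 and 3 and 48 and 64 without PEG SA190 replicates 1 and 2.

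**Figure D2:**
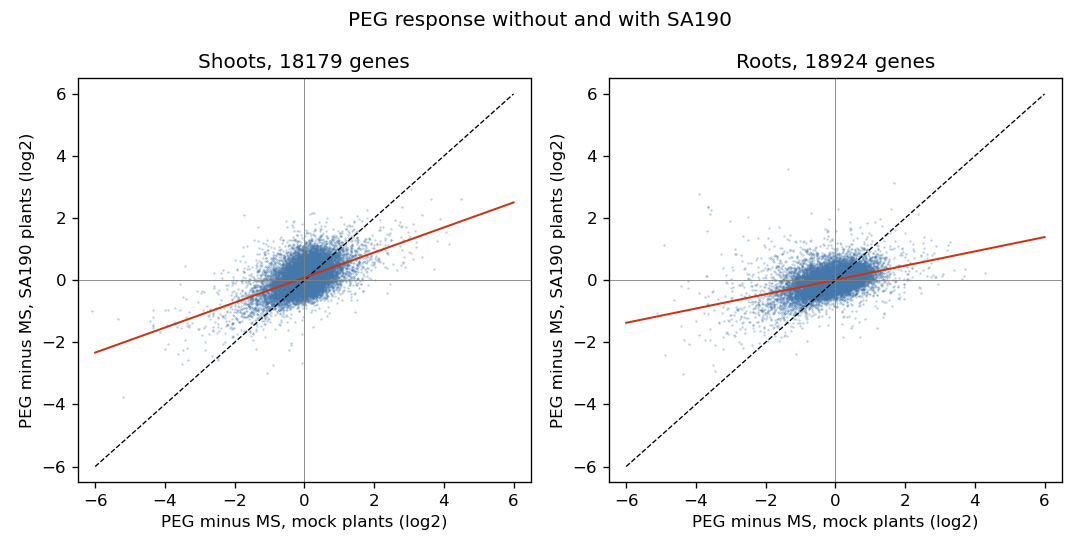
Each point is a tested gene, placed by its log2 difference between PEG and MS in mock plants (x axis) and in SA190 plants (y axis), for shoots (left) and roots (right). The red fitted line has a slope of 0.403 in shoots and 0.230 in roots, and the dashed line marks equal effects.

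The SA190 effect under PEG differed from that on MS for 419 shoot genes (316 more positive under PEG, 103 more negative) and 2685 root genes (1722 and 963), by a test of the interaction in limma. In roots the interaction was 5.25 ± 0.47 for MRN1, 4.54 ± 0.29 for HAK5, -3.55 ± 0.19 for ACC2 and -2.92 ± 0.18 for GMI1. In shoots it was 5.11 ± 0.74 for DIN1, 3.37 ± 0.57 for BGAL4, -2.09 ± 0.26 for APL3 and -2.33 ± 0.29 for BGLU11 (AT1G02850). By list, 14 of 22 ABA and drought response genes in roots had a more positive SA190 effect under PEG and 1 a more negative one, and the counts were 13 and 1 of 27 aquaporins and 12 and 0 of 23 light-harvesting genes. Leaving out shoot PEG SA190 replicate 1 or 2 gave 27 or 277 shoot genes. DIN1 and BGAL4 no longer passed without replicate 1, nor DIN1 with voom. Without shoot mock replicate 1 or 2 the count was 99 or 212, without PEG replicate 1 or 2 it was 186 or 127, and without shoot SA190 replicate 1 it was 653. Library weights gave 860 genes, voom 639, a fit on all 23 libraries 1115 and quantile normalisation 629, with 55.8% more positive against 75.4%. For roots, SA190 replicate 2, PEG replicate 3, PEG SA190 replicate 1 or 2 left out gave 1603, 1785, 1700 and 1692, library weights 10789, and quantile normalisation 53.7% more positive against 64.1%.

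Between the tissues the SA190 effect under PEG differed for 1496 of 19420 genes, 1119 more positive in roots and 377 more negative. HAK5 had an effect of 4.92 in roots and -1.45 in shoots, a difference of 6.37 ± 0.36. MLP328 had effects of 4.67 and -0.38, a difference of 5.05 ± 0.39. DIN1 rose by 5.76 in shoots and 2.10 in roots, a difference of -3.66 ± 0.66. For ASN1 the effects were 2.87 in shoots and -0.66 in roots, a difference of -3.53 ± 0.51. Anthocyanin genes had a more positive effect in roots in 10 of 12 cases and ABA and drought response genes in 12 of 25, with 0 and 1 more negative. Without shoot PEG SA190 replicate 1 the count was 864. Pseudocount 0.5 gave 931 genes and library weights 3945, and quantile normalisation moved the share of more positive differences from 74.8% to 64.5%.

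Aquaporins, the water and solute channels in the title of the series, fell with PEG in both tissues and rose with SA190 under PEG in roots. In roots 18 of 27 tested members fell with PEG and 4 rose (18 and 4 adjusted over the list alone), with a median of -0.80 (camera adjusted p = 0.00121, and adjusted p = 0.566 with an estimated correlation). With SA190 under PEG 14 rose and 3 fell (14 and 4 adjusted over the list alone), with a median of 0.77 (adjusted p = 0.0012, and 0.566 with an estimated correlation). The tonoplast genes TIP2;3 (AT5G47450) and TIP2;2 (AT4G17340) fell by 3.12 ± 0.46 and 2.98 ± 0.27 with PEG and rose by 3.05 ± 0.46 and 2.57 ± 0.27 with SA190. TIP1;1 (AT2G36830) and TIP1;2 (AT3G26520) fell by 2.19 ± 0.26 and 2.46 ± 0.28 and rose by 2.06 ± 0.26 and 2.34 ± 0.28. The plasma membrane genes PIP1;3 (AT1G01620), PIP2;1 (AT3G53420) and PIP2;4 (AT5G60660) fell by 1.87 ± 0.19, 1.61 ± 0.26 and 2.01 ± 0.21 and rose by 1.64 ± 0.19, 1.57 ± 0.26 and 1.92 ± 0.21. PIP2;5 (AT3G54820) and the boric acid channel gene NIP5;1 (AT4G10380) rose with PEG by 1.43 ± 0.16 and 1.27 ± 0.12 and fell with SA190 by 1.32 ± 0.16 and 0.56 ± 0.12. On MS 0 of 27 root aquaporins passed for SA190 (7 lower adjusted over the list alone), and in SA190 roots PEG raised 2 and lowered 1 (3 and 3 adjusted over the list alone).

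In shoots PEG lowered 12 of 24 aquaporins and raised 2 (13 and 2 adjusted over the list alone; median -0.68, adjusted p = 5.62e-05, and 0.406 with an estimated correlation). TIP2;2 fell by 2.44 ± 0.19, TIP2;1 (AT3G16240) by 2.06 ± 0.28, PIP2;7 (AT4G35100) by 1.70 ± 0.19, PIP2;1 by 1.48 ± 0.18 and PIP1;1 (AT3G61430) by 1.33 ± 0.17, while NIP5;1 rose by 1.03 ± 0.23. With SA190 under PEG 3 shoot aquaporins rose and 3 fell (5 and 3 adjusted over the list alone; adjusted p = 0.0985, and 0.034 to 0.0468 without PEG replicate 1, PEG replicate 3 or PEG SA190 replicate 2). TIP1;2, TIP2;2 and PIP1;3 rose by 1.23 ± 0.28, 1.09 ± 0.21 and 0.93 ± 0.20. NIP5;1, PIP2;5 and PIP1;4 (AT4G00430) fell by 1.16 ± 0.25, 0.87 ± 0.24 and 0.57 ± 0.16. Each of the 6 lost its call without shoot PEG SA190 replicate 1. On MS SA190 gave shoot aquaporins a median of -0.47 with 0 members passing and 14 of 24 lower adjusted over the list alone (adjusted p = 1.87e-06, and 0.391 with an estimated correlation). The SA190 effect under PEG was more positive in roots than in shoots for 7 of 27 aquaporins and more negative for 0. Reads of close copies in this family, such as PIP2;2 and PIP2;3, could have been divided between them, so single values of such copies are uncertain.

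**Figure D3:**
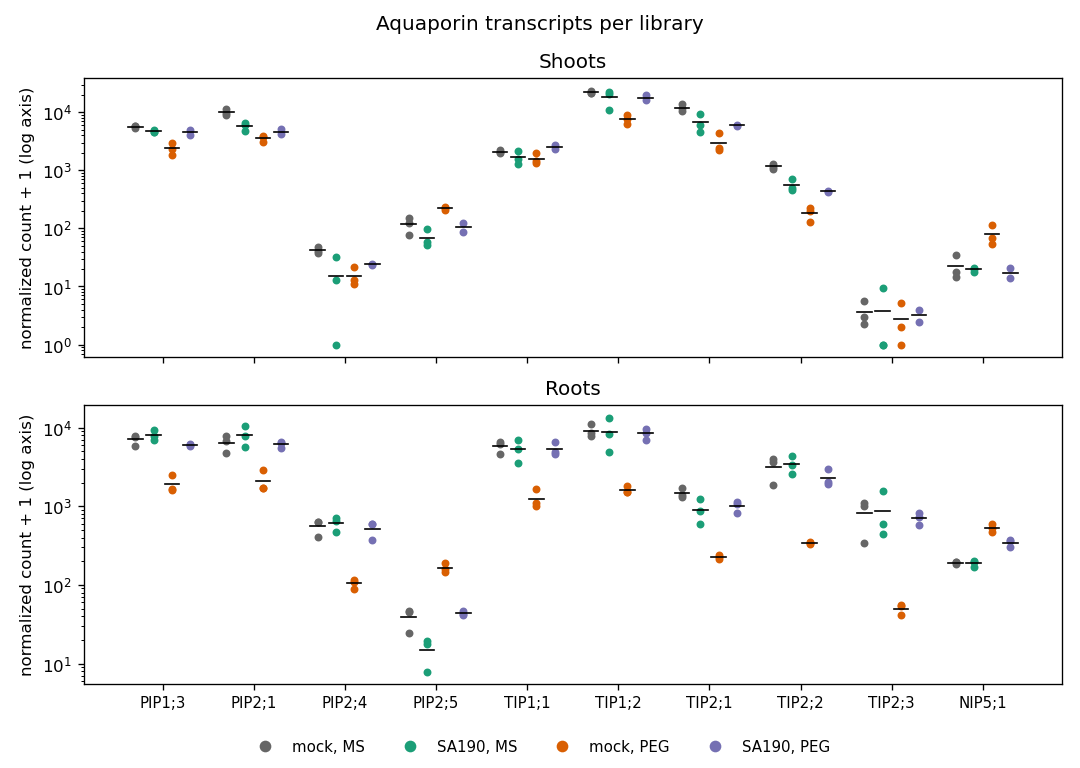
Points are libraries and black bars group means of the normalised count plus 1 (log axis) for 10 aquaporin genes in shoots (top) and roots (bottom), coloured by treatment. In roots the PEG group of TIP2;3 had a mean of 48.9 beside 822 in mock roots and 708 with PEG and SA190, with n = 3 each.

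Of the 180 list tests 49 had a camera adjusted p under 0.05, and 0 did with an estimated correlation. Among lists not yet described, those of salicylic acid response, pattern-triggered immunity, ethylene-jasmonate defence, nitrate uptake, antioxidant enzymes, suberin, heat shock and seed storage passed in 0 comparisons, as did ABA metabolism and proline and raffinose metabolism. In roots PEG raised 4 and lowered 7 of 19 immunity genes, raised 0 and lowered 4 of 7 salicylic acid genes and raised 1 and lowered 9 of 18 suberin genes (4 and 7, 0 and 4, and 1 and 9 adjusted over the list alone). The medians of these lists were -0.24, -0.47 and -0.48 in PEG roots, against 0.17, 0.13 and 0.33 in PEG shoots. For nitrate uptake the root counts were 1 and 1 of 8, for antioxidant enzymes 2 and 1 of 11 and for heat shock 2 and 2 of 6 (1 and 0, 2 and 1, and 2 and 2 adjusted over the list alone). For ethylene-jasmonate defence they were 0 and 2 of 3 and for proline and raffinose 3 and 4 of 9 (0 and 2, and 3 and 4 adjusted over the list alone). The jasmonate list passed in PEG roots, where 1 of 11 rose and 5 fell (1 and 6 adjusted over the list alone; adjusted p = 0.0447). It also passed with SA190 under PEG, where 4 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.0443). Both values exceeded 0.05 without root mock replicate 2, root PEG replicate 2 or 3 or root PEG SA190 replicate 1, and the second also without root PEG SA190 replicate 2. The highest were 0.0877 and 0.0901, and both were 0.581 with an estimated correlation. Auxin response genes in PEG roots fell in 8 of 12 cases and rose in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.0331, at most 0.0516 without root PEG replicate 2 or 3, and 0.432 with an estimated correlation), with IAA3 (AT1G04240) at -1.58 ± 0.13. Phosphate starvation genes with SA190 in PEG roots fell in 6 of 16 cases and rose in 1 (6 and 2 adjusted over the list alone; adjusted p = 0.0454, and 0.426 with an estimated correlation). That value reached up to 0.0912 with root mock replicate 2, SA190 replicate 1 or 3, PEG replicate 1 or PEG SA190 replicate 3 left out. In SA190 plants PEG gave passing values for iron deficiency and anthocyanin genes in shoots (adjusted p = 0.0454 and 0.0447, and 0.618 and 0.581 with an estimated correlation), which leaving out single libraries raised to 0.0966 and 0.227. The iron median of 0.32 was -0.06 after quantile normalisation and -0.07 with voom. In SA190 roots the sulfur deficiency, auxin response and root marker lists passed with PEG (adjusted p = 0.012, 0.011 and 0.000477, and 0.391, 0.426 and 0.406 with an estimated correlation). The first was 0.0595 without root SA190 replicate 2 and the second 0.0524 without root PEG SA190 replicate 3. Of the seed storage genes 1 of 14 was expressed highly enough to be tested, in shoots, with 0 calls.

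**Figure D4:**
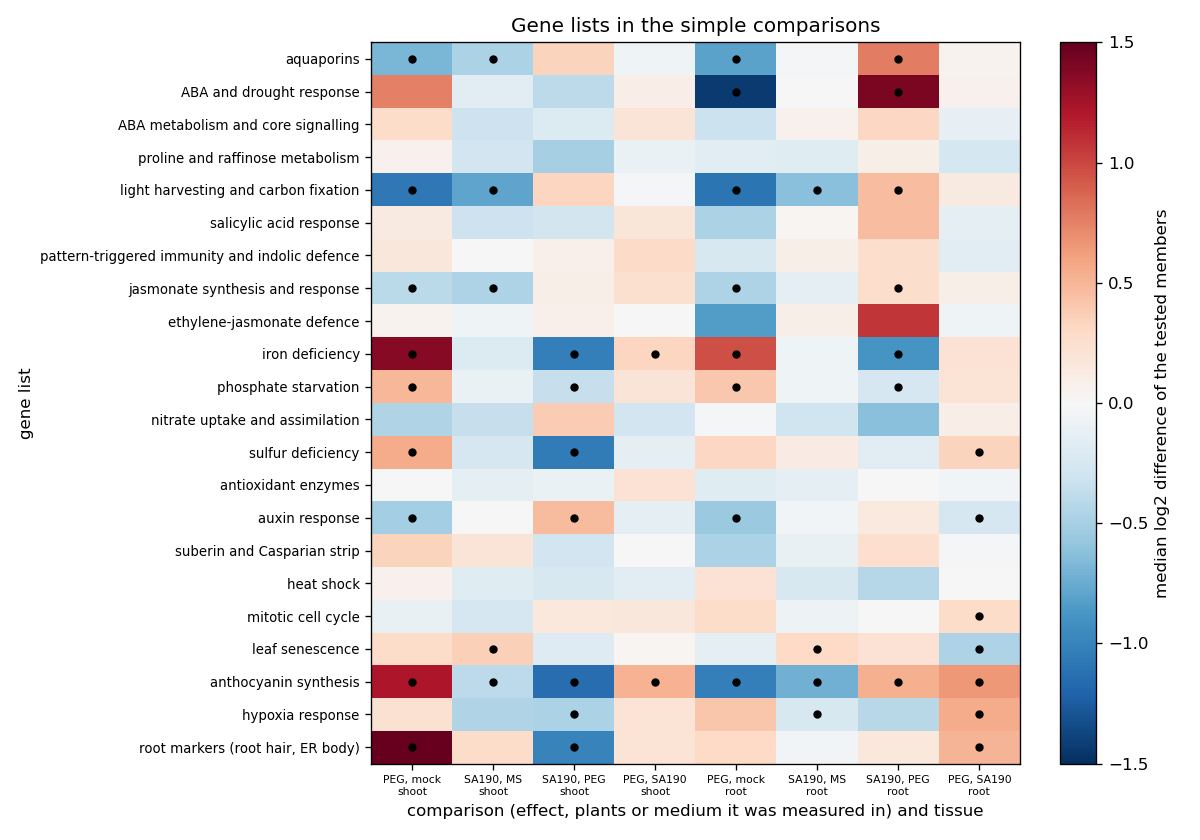
Colours give the median log2 difference of the tested members of each gene list (rows) in each comparison (columns), on a scale that ends at 1.5 in both directions, and dots mark a camera adjusted p under 0.05 with the preset correlation. Iron deficiency genes had medians of 1.36 with PEG and -1.02 with SA190 under PEG in shoots, and 0.97 and -0.88 in roots.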

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

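Among the tests of this part, the placing of root libraries on an axis made without them, the estimate of shoot RNA carried over into roots and the search for an unlike SA190 shoot library were chosen only after the result was seen.

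A difference between groups, tested as an interaction in limma, flagged the SA190 effects of 419 shoot genes and 2685 root genes, which differed between PEG and MS. A difference between tissues flagged the PEG effect in mock plants of 3711 genes and the SA190 effect under PEG of 1496 genes. For the PEG effect the root minus shoot differences were 4.23 for ASN1, 4.19 for PHI-1, 3.76 for GDPD2, -5.13 for UMAMIT17, -5.30 for MLP328 and -6.77 for HIS1-3. For SA190 under PEG they were 6.37 for HAK5, 5.05 for MLP328, 4.76 for CYP76G1, -3.29 for ACC2, -3.53 for ASN1 and -3.66 for DIN1. When library labels were exchanged between groups within both parts of the comparison, 8 of 100 splits gave as many genes for the root interaction as the 2685 observed, with a highest other count of 4260. All 7 others kept PEG roots apart from PEG roots with SA190, as 12 of the 99 other splits did, and splits that mixed them gave at most 435 genes. By the rule set beforehand, 8 of 100 splits would leave a random grouping open for the root interaction. The 7 others still carried the difference between PEG roots with and without SA190. They do not stand for random groupings, so the rule cannot decide here. For the tissue difference of the PEG effect 1 of 100 splits, the real one, gave 3711 genes and the next 3453. The 3453 came from the 12 of 99 other splits that left 1 part of the comparison as labelled and so kept a PEG effect. The remaining splits reached 2924. For the tissue difference of SA190 on MS the splits gave up to 80 genes. With 0 observed, all 100 had to give at least as many, so this test decides nothing. The 10 splits of 6 libraries are too few to judge a comparison: the real split (1 of 10) gave 3722 genes against at most 0 for PEG in mock shoots, 1 against 0 for SA190 on MS in shoots, 7883 against 84 for PEG in mock roots, 60 against 0 for SA190 on MS in roots, 6162 against 0 for SA190 under PEG in roots and 1410 against 0 for PEG in SA190 roots.

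Root genes moved by PEG in mock plants moved back in PEG roots with SA190. Independent noise in the shared PEG libraries is argued against as the whole cause, since the covariance was 16.5 times that of simulated unchanged groups. The simulation gave every library its own noise, so it cannot judge a shift common to the PEG libraries that did not come from PEG. A difference in rRNA content is argued against, because within root groups the library with the least rRNA lay only 0.04 (SD 0.07) nearer to PEG roots than the one with the most, on an axis from mock roots at 0 to PEG roots at 1. On that axis the 3 PEG SA190 libraries (0.16, 0.17 and 0.30) lay far below the PEG roots and exceeded the highest MS library by only 0.06. The rule set beforehand asked for more than the SD of the MS libraries, also 0.06, so this axis alone cannot decide. An axis chosen later ran from MS roots at 0 to PEG SA190 roots at 1 and was made without the library placed. On it the lowest of the 3 exceeded the highest MS library by 0.44, with an SD of the MS libraries of 0.21. That argues against an MS library among the 3, although root mock replicates 2 and 3 lay at 0.37 and 0.32. Harvest at another time of day was not tested for this reversal. The median of morning clock genes minus that of evening ones was -0.96 for SA190 under PEG in roots, where 6 of them passed. On MS it was -0.71 with 2 passing, and there SA190 changed 60 root genes. An effect of SA190 on the response of roots to PEG, or on how much stress reached them, also stays open as untested.

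Light-harvesting transcripts were lower in PEG roots than in mock roots. Carry-over of shoot tissue is argued against as the whole cause: after taking out the largest share of shoot RNA that the abundant members allow (0.006% to 0.639%, highest in root mock replicate 1), the median moved from -1.10 to -0.56, and the members of 23 that passed as lower went from 17 to 11. Without root mock replicate 1 the median moved from -0.81 to -0.70. A partial contribution of carry-over and an effect of PEG on plastids of the root stay open.

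SA190 on MS called 1 gene in shoots. Low depth of the shoot SA190 libraries is argued against only as a cause that would hide an effect as large as that of PEG. Thinning the PEG shoots to that depth still called 3154 to 3243 genes, against 3722 without thinning. Whether depth hid a smaller effect cannot be judged from this, because the PEG effect is large. In simulations of SA190 on MS in shoots 3% of 1.5-fold and 32.8% of 2-fold changes were found. A library unlike the others cannot be told apart: without SA190 replicate 1, which had the lowest mean correlation with the other 2 (0.932), 17 genes passed, between the bounds set, and without replicate 2, which had the highest (0.950), 228 did. Replicate 1 stood apart on the second principal component of shoots, at 58.0 against -11.3 and -16.3 for replicates 2 and 3. Its library weight of 0.186 was the lowest among shoots. It is also the shallowest shoot library, so depth and unlikeness cannot be separated here. A small effect of SA190 on shoots kept on MS stays open as untested.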

How the results depend on the processing

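Of the tests of this part, voom on recovered reads and leaving out the shallowest library of each tissue (shoot SA190 replicate 1 and root mock replicate 3) were chosen only after the results were seen. No named gene changed sign with its call under any setting: of 545 gene comparisons, 358 kept their side of the threshold in every setting and 187 did not. Library weights gave, in the order PEG in mock plants, SA190 on MS, SA190 under PEG and interaction, 6965, 6, 3195 and 860 genes in shoots and 12117, 6378, 12237 and 10789 in roots, 9276 for PEG in SA190 roots, and 7887, 36 and 3945 for the tissue differences of PEG, SA190 on MS and SA190 under PEG. Root weights ran from 0.213 to 10.964, the highest on root SA190 replicate 2. Fits on the groups of a comparison alone gave 5804, 0, 2618 and, for PEG in SA190 plants, 88 in shoots, and 0 for SA190 on MS and 2141 for PEG in SA190 plants in roots. A fit on all 23 libraries gave 417 for SA190 on MS, 2281 for SA190 under PEG, 2102 for PEG in SA190 plants and 1115 for the interaction in shoots, and 28 for SA190 on MS in roots. Quantile normalisation gave 4 for SA190 on MS and 629 for the interaction in shoots, and 99 for SA190 on MS in roots. For the tissue difference of SA190 on MS, pseudocounts 0.5, 1 and 5 gave 2, 2 and 1 and no filter 3, and pseudocount 0.5 gave 931 for that of SA190 under PEG. Voom gave 5720 for PEG in mock plants, 3305 for SA190 under PEG and 639 for the interaction in shoots, and 33 for SA190 on MS in roots. Without the shallowest libraries the counts were 17 for SA190 on MS, 2325 for SA190 under PEG and 653 for the interaction in shoots, 978 for SA190 on MS in roots, 1582 shoot genes in opposite directions and 65 for the tissue difference of SA190 on MS. Fewer genes pass when at least 2-fold on the deposited scale is asked: 1394, 650 and 452 in shoots for PEG in mock plants, SA190 under PEG and PEG in SA190 plants, 1797, 23, 1305, 287 and 1171 in roots for the 5 comparisons with SA190 on MS second and the interaction last, 2077 for the tissue difference of PEG, and 430 shoot and 1022 root genes in opposite directions. With an estimated correlation 0 list tests passed. Except for the 2-fold threshold and the left-out libraries, the cause was not tested.

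With single libraries left out the counts ran from 2435 to 5054 (PEG in mock plants), 1 to 228 (SA190 on MS), 318 to 2325 (SA190 under PEG), 54 to 1523 (PEG in SA190 plants) and 27 to 653 (interaction) in shoots. In roots they ran from 6152 to 8556, 0 to 978, 4273 to 6862, 685 to 1865 and 1603 to 4015. Tissue differences ran from 2847 to 4531 (PEG), 0 to 187 (SA190 on MS) and 864 to 2006 (SA190 under PEG), genes in opposite directions from 288 to 1582 in shoots and 3772 to 5411 in roots, passing list tests from 45 to 57, and the correlation of PEG effects from 0.454 to 0.552 in shoots and 0.311 to 0.480 in roots. Leaving out a PEG SA190 shoot library leaves 1, which is then assumed to vary like the other groups. Of these left-out counts and correlations 200 stayed within 1.5 times or kept their place and 53 moved, and of the other settings 128 and 55. Of the remaining counts of genes called in 2 comparisons 82 stayed and 79 moved with single libraries left out, and 3 and 11 in the other settings. The 2 planned count-model fits were not run.

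The replicate number as a block gave 902 genes for SA190 under PEG, 369 for PEG in SA190 plants and 223 for the interaction in shoots, and moved no other count of calls by more than 1.5 times; of the 49 list tests that passed it kept 47. Those lost were phosphate starvation with SA190 in PEG roots (adjusted p = 0.0552) and anthocyanin genes with PEG in SA190 shoots (0.106), and those gained were salicylic acid response with SA190 in PEG shoots (0.0361) and hypoxia with SA190 on MS in shoots (0.0295). The numbers were not taken to pair the samples, since not every correlation exceeded 0.1: same-numbered libraries of a tissue, after group means were taken out, correlated from -0.52 to 0.49 in roots (7 of 18 above 0.1) and from -0.52 to 0.19 in shoots (4 of 15), shoots and roots of the same number and treatment from -0.03 to 0.61 (9 of 11 above 0.1, median 0.27 against -0.21 for other numbers), and 2 of 11 shoot and 5 of 12 root libraries correlated best with their own number. For shoots and roots of the same number and treatment this rule does not exclude pairing. Deviations from a group mean sum to 0, so the median of -0.21 follows in part from that of 0.27. The tissue differences treat shoots and roots as independent. With shoot and root of the same number and treatment as the block they gave 4113 (PEG), 0 (SA190 on MS) and 1527 (SA190 under PEG). In simulations of SA190 on MS in shoots 32.8% of 2-fold and 3% of 1.5-fold changes were found, so most weak changes would be missed at the simulated spread. That spread was no smaller than the median of genes at a similar level, so the share missed in the real libraries may differ. Depth limits low values: 1 read was worth 19.1 normalised counts in shoot SA190 replicate 1.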

Other observations

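The gene families, the comparison of PEG with SA190 against mock plants and the tests of harvest time for SA190 on MS and under PEG and of carried-over shoot tissue for SA190 on MS were chosen only after the results were seen. The 11 further sugar genes were chosen after DIN1 and ASN1 were seen and before their own values were, as was the test of harvest time for PEG in mock shoots.

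Among gene families grouped by symbol, the cytochrome P450 genes of roots had the smallest adjusted p with the preset correlation: of 137 tested CYP genes in root tissue, PEG raised 13 and lowered 78 (median -0.52, camera adjusted p = 2.12e-06) and SA190 under PEG raised 76 and lowered 9 (median 0.51, adjusted p = 2.09e-08, and both 0.779 with an estimated correlation). The MLP family of major latex protein-like genes fell with PEG in 6 of 6 root cases (median -2.85) and rose with SA190 under PEG in 5 (median 2.67). CIPK protein kinase genes, which act with calcium sensors, fell in 12 of 19 root cases with PEG (median -0.72) and rose in 10 with SA190 under PEG. UMAMIT genes rose with SA190 in PEG root tissue in 16 of 33 cases and fell in 1 (median 0.46). In shoot tissue PEG lowered all 6 TUA alpha-tubulin genes and raised 10 of 22 BGLU beta-glucosidase genes with 1 lower, and it raised 7 of 14 ABCC transporter genes (median 0.74), of which 6 fell with SA190 under PEG (median -0.68). With an estimated correlation 0 of 2104 family tests passed.

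Further genes that rise in sugar starvation followed DIN1 and ASN1 in shoots. TPS9 (AT1G23870) fell by 2.11 with PEG in mock shoots and rose by 1.40 with SA190 under PEG, IVD (AT3G45300) of leucine breakdown fell by 2.34 and rose by 1.46, and DIN4 (AT3G13450) fell by 2.43 and rose by 1.83. All 11 such genes fell in PEG shoots (median -2.06), and 10 rose with SA190 under PEG (median 1.40). In roots 11 fell (median -1.94) and 9 rose (median 1.17), but ASN1 did not follow, at -0.19 with PEG and -0.66 with SA190 under PEG. The shoot values are consistent with more sugar in PEG shoots and less when SA190 was present, a hypothesis that no sugar measurement here tests. Harvest at another time of day cannot be told apart for PEG shoots, where morning minus evening clock genes gave -0.56, between the bounds set beforehand. For PEG in mock roots, where the 11 sugar genes also fell, that difference was 0.34, opposite in sign and below the lower bound set for shoots. For SA190 under PEG in shoots the same difference was -1.20, which a harvest of these plants at another time of day fits. The rise of these genes with SA190 could come from that as well. On MS, however, the difference for SA190 in shoots was -1.18, and only DOX1 passed. DIN1 stood there at 34871 normalised counts against 22455 in mock shoots, and ASN1 at 27850 against 32465. With PEG and SA190 these 2 genes reached 17798 and 11163, below their levels in mock shoots. On MS they had not been lowered, so the values there cannot decide whether harvest time caused the rise under PEG. The -0.56 for PEG in mock shoots has the same sign, while the sugar starvation genes fell.

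The median of 6 morning clock genes minus that of 6 evening ones was -1.18 in shoots and -0.71 in roots for SA190 on MS, and -1.20 and -0.96 for SA190 under PEG. Of the 12, 0 in shoots and 2 in roots passed on MS and 2 and 6 under PEG, and in roots on MS the morning genes PRR9 and RVE8 had differences of 0.51 and 0.10. A harvest of SA190 plants at another time of day fits these medians and could also account for the lower light-harvesting transcripts on MS. Under PEG, where the clock medians differed by at least as much, light-harvesting genes had medians of 0.46 in roots and 0.32 in shoots. The shoot median was -0.29 after quantile normalisation. PEG alone had lowered this list in both tissues, so the values under PEG do not decide the question for MS. For the roots on MS, shoot tissue carried over into mock samples cannot be told apart, since taking out the largest possible share moved their median from -0.63 to -0.25, between the bounds set. Without root mock replicate 1 that median moved from -0.49 to -0.41. An effect of SA190 on the clock itself stays open as untested.

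Against mock plants on MS, plants with both PEG and SA190 differed in 1043 shoot genes (385 higher, 658 lower) and 383 root genes (97 higher, 286 lower), a comparison added after the others.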
